A study of Mus musculus with 21 samples.

How the data were processed

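RNA sequencing libraries of 2CLCs, ESCs, EpiSCs and MEFs (12 libraries) and of ESCs at 0, 60 or 80 mM sodium lactate (9 libraries) were analysed, with 3 libraries per group and groups taken from the labels. Per the labels, total RNA was taken with Trizol and libraries were made with a TruSeq kit. The submitters' processing notes name HISAT2 2.0.4 for alignment to mm10 and StringTie 2.1.4 for quantification. The values are FPKM as deposited by the authors, in a table for the cell states and another for lactate, and the authors' annotation is not given in the sources used here. Read counts were not used here, and the depth of each library is unknown: FPKM times gene length did not fall on a common step in single-exon genes (1.41 to 5.98% of them shared the commonest value), so no counting intervals are given.

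The cell-state table holds 21199 entries for 21161 gene names, each with a maximum of at least 0.5 FPKM, and the lactate table holds 55410 entries for 55291 names, of which 22426 are at 0 in every library. Entries that share a name were summed. For the cell states, 35 names stand more than once, with identical values in every library but the first column, which looks like a fault of joining, and for lactate 112 names stand more than once; none of these is named in the text. Some exact zeros beside high replicates may be failed estimates. Gene names were placed with GENCODE M21 on GRCm38, which knows 20640 and 53292 of the names.

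Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 libraries of a table were tested. Linear models were fitted with limma 3.58.1 in R 4.3.3, with all groups of a table in a single fit and moderated variances with a mean trend, and p-values were adjusted with the Benjamini-Hochberg method within a comparison at a threshold of 0.05. The comparisons were 2CLC, EpiSC and MEF against ESC, 60 and 80 mM against 0 mM, and 80 against 60 mM. The tables were normalized separately, and groups were tested against each other only within a table. The ratio of the rise of the 2C genes at 80 mM to their 2CLC level less their ESC level sets levels from both tables side by side, with a bootstrap interval over genes, and does not account for the separate normalization. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures.

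Gene lists (30, each with at least 5 measured members) were written from general knowledge, and tested with camera in limma at a preset correlation of 0.01 between genes, which compares a list with all other genes, with adjustment over all lists and comparisons of a table. Counts of members are also given with p-values adjusted over the list alone. Genes changed by at least 1 (log2) and called in 2CLCs, EpiSCs or MEFs were tested as sets in the lactate table. The overlap of the 60 and 80 mM calls was set against 100 simulations with no change, in which both doses had common simulated controls.

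The text names, per comparison, the 6 largest rises and 6 largest falls among called genes with at least 5 FPKM in the higher group, groups that do not overlap (by chance 10% of genes at 3 against 3) and no predicted-gene name, and per list its anchor genes and up to 4 further members. The comparisons, thresholds, lists, rule for names and alternatives were set before the data were examined, except where stated.

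The alternatives were a pseudocount of 0.1 or 5, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, no mean trend, a fit of only the compared groups, leaving out each library in turn, a replicate block, a minimum change of 1 (2 for the gene sets), camera with an estimated correlation, fry, and the 2CLC gene set without genes higher in MEFs. Added after seeing the data were fits without repeated names and with EpiSC replicate 1 or 60 mM replicate 1 left out of the shared spread. The pipeline was tested on simulated data with the spread of each comparison and 200 changed genes, all above 5 FPKM in the second group. Recovery of lower genes was not simulated. Genes were simulated as independent, so the random lists do not check the preset correlation. It recovered 47.8 to 97% of changes of 0.5, 92.5 to 100% of changes of 1 and 100% of changes of 2 (log2), with 3.01 to 6.15% false calls, and 0 to 2 of 20 random lists had a p under 0.05.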

Results

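RNA was sequenced from mouse cells of the line OG2, as the labels name it, in 21 libraries that fall into 2 tables. The cell-state table holds 3 libraries each of 2-cell-like cells (2CLCs, cells with transcripts of the 2-cell embryo), embryonic stem cells (ESCs), epiblast stem cells (EpiSCs, which stand for a later, primed form of pluripotency) and mouse embryonic fibroblasts (MEFs). The lactate table holds 3 libraries each of ESCs with 0, 60 or 80 mM sodium lactate. All values are FPKM as deposited, and the number of reads behind them is unknown. Library sums ranged from 375926 to 519915 FPKM in the cell-state table and from 396792 to 409131 in the lactate table, and between 12266 and 13124 genes per library reached 1 FPKM. Levels below are mean FPKM ± SD over 3 libraries, log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near 0, and adjusted p-values come from limma with Benjamini-Hochberg adjustment. The 2 tables were normalized separately, so groups were tested against each other only within a table.

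2CLCs were compared with ESCs to ask which transcripts mark the 2-cell-like state. Zscan4c, a member of a gene cluster switched on in the 2-cell embryo, stood at 5910 ± 362 FPKM in 2CLCs and 2.34 ± 0.2 in ESCs (SD, n = 3), a 2530-fold difference with a log2 fold change of 10.79 (adjusted p = 6.61e-16). Zfp352 rose from 0.0645 ± 0.0445 to 212 ± 13.3 FPKM and Tcstv3 from 0.456 ± 0.0632 to 1070 ± 72.6, and Duxf3, a copy of the gene for the transcription factor that starts this programme, rose from 0.0897 ± 0.0208 to 64.5 ± 6.39. Of the 53 measured genes of the 2C list, 51 rose, Eif4e3 fell (log2 fold change -0.36, or -0.30 with median-of-ratios scaling, and adjusted p = 0.147 with a pseudocount of 5) and 1, Zfp750, did not pass the test. Zfp750, and each single member of a list named below only for its call, was chosen after its values were seen. The list's median log2 fold change was 8.32 (camera adjusted p = 7.31e-43, and 0.000277 with an estimated correlation). Many members, such as Zfp352 and Tcstv3, stood under 1 FPKM in ESCs. Members that were as low in EpiSCs and MEFs passed the filter only through 2CLCs. For those, the filter fixed the direction in the count and in the list test. These 2C genes held 11.65% ± 0.591 of all FPKM in 2CLCs and 0.0119% in ESCs. Zscan4c lies on chromosome 7 at 11005745 to 11010547, Tcstv3 on chromosome 13 at 120316878 to 120318178, Zfp352 on chromosome 4 at 90218820 to 90225702 and Duxf3 on chromosome 10 at 58229979 to 58232675 (GRCm38). Zscan4, Tcstv and Dux copies are nearly identical in sequence, so the split of their FPKM among copies is uncertain.

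**Figure D1:**
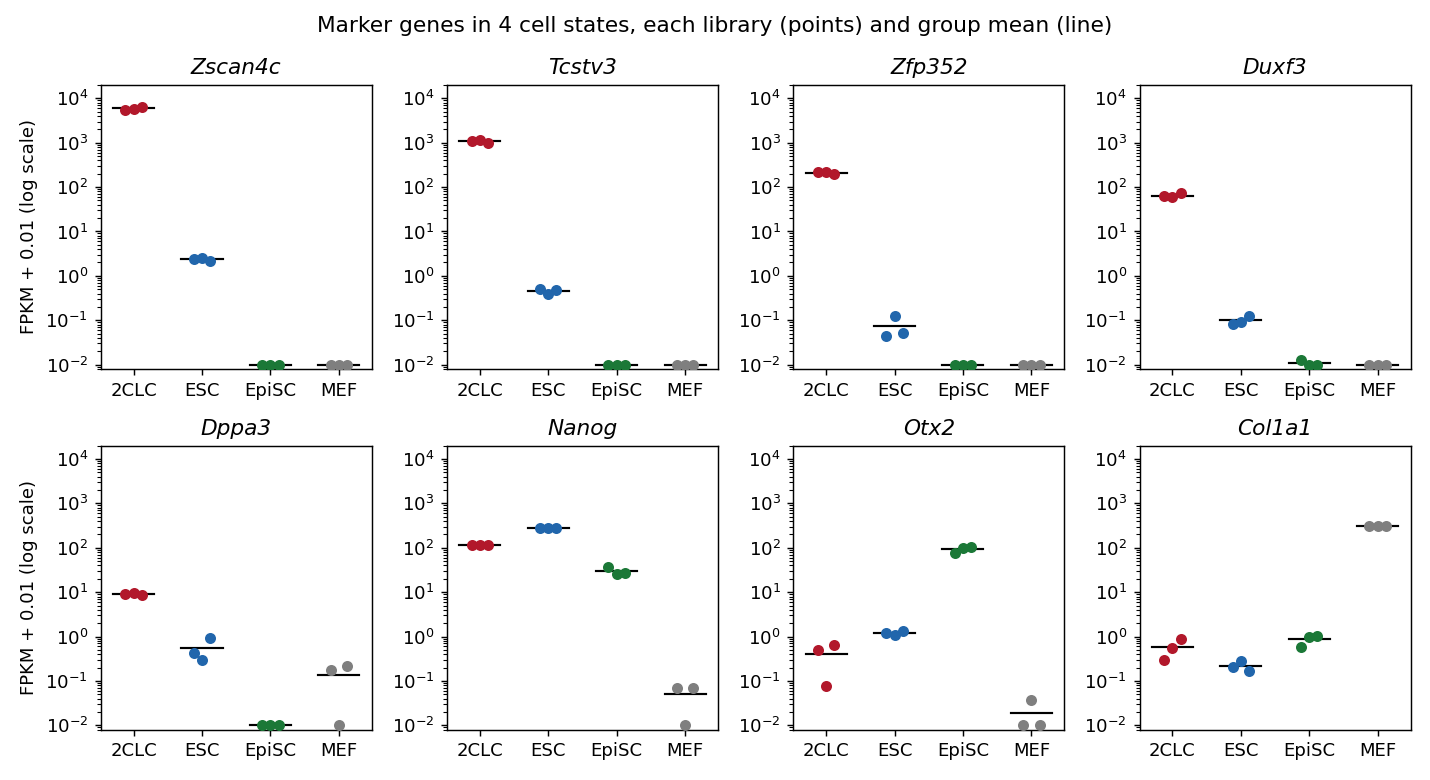
FPKM + 0.01 on a log axis of 8 marker genes in 2CLCs, ESCs, EpiSCs and MEFs, with a point for each library and a line at the mean of 3. Zscan4c lay at 5910 FPKM in 2CLCs and was listed at 0 in every EpiSC and MEF library, while Col1a1 was highest in MEFs at 310 FPKM.

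Across all genes, 12516 of 16358 tested changed between 2CLCs and ESCs, 3296 higher and 9220 lower, of which 2046 and 4339 differed by at least 1 on the log2 scale. Without 2CLC replicate 1, 2 or 3 the higher genes numbered 1766, 1729 and 1901, as fewer genes pass the filter of 3 libraries. The median of all genes fell by 0.458 on the log2 scale, and with median-of-ratios scaling the split became 6305 higher and 5198 lower, while with quantile normalization it was 3828 and 8202. For some genes and lists the change is also given relative to that median. This takes the same value from every gene, while median-of-ratios scaling moved lists by unlike amounts. The core spliceosome median went from -0.62 to 0.13 and the fibroblast median from 0.02 to 0.11. A change relative to that median therefore does not stand in for rescaling.

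Pluripotency genes, which keep ESCs undifferentiated, moved in both directions in 2CLCs. Esrrb fell from 285 ± 5.79 to 43.5 ± 8.26 FPKM (log2 fold change -2.70, or -2.24 relative to all genes), Klf4 from 69.4 ± 1.16 to 9.86 ± 0.805, Zfp42 from 318 ± 1.37 to 57.9 ± 3.27 and Sox2 from 131 ± 1.22 to 19.9 ± 4.41. Nanog fell less, from 277 ± 1.85 to 114 ± 1.29 FPKM (-1.27, or -0.81 relative to all genes, adjusted p = 5.28e-07). Dppa3 rose from 0.53 ± 0.323 to 9.12 ± 0.465 FPKM and Fbxo15 from 51.7 ± 0.682 to 908 ± 68.9. Of the 32 naive pluripotency genes 6 rose, 23 fell and 3 did not pass, and of the 18 core pluripotency genes Dppa2 rose, 14 fell and 3 did not pass. Neither list passed the test (camera adjusted p = 0.142 and 0.0541, medians -1.21 and -1.46). With median-of-ratios scaling 10 naive genes rose and 19 fell (median -0.55), and 4 core genes rose and 11 fell (median -0.69). The core list passed with camera under 5 alternatives (adjusted p from 0.013 to 0.0473) and the naive list with no filter (0.0353). With fry, which tests a list against no change and not against other genes, they passed at 1.22e-07 and 6.75e-08. Most of the 30 lists passed with fry in this comparison, so this does not set the pluripotency lists apart. Pou5f1, the gene for OCT4, stood at 552 ± 19.1 FPKM in 2CLCs and 779 ± 3.4 in ESCs (log2 fold change -0.50, adjusted p = 0.000151), and its direction reversed to 0.28 with median-of-ratios scaling. The RNA-binding protein gene Lin28a fell from 117 ± 3.04 to 6.95 ± 1.02 FPKM and Sall1 from 43.5 ± 1.49 to 1.87 ± 0.706.

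Among single genes of growth control, Myc fell from 42 ± 1.77 to 1.61 ± 0.335 FPKM, Spry4 from 37.3 ± 0.635 to 1.3 ± 0.524 and Dusp6 from 28.1 ± 2.19 to 0.796 ± 0.201. Bmp4 fell from 17.6 ± 1.35 to 0.898 ± 0.348 FPKM, Ccnd1 from 63.6 ± 0.704 to 6.07 ± 1.06 and Ccne1 from 123 ± 1.02 to 27.3 ± 1.96. In the G1/S and DNA replication list 3 of 29 genes rose, 23 fell and 3 did not pass (median -0.80, camera adjusted p = 0.0264, and 0.274 with an estimated correlation). With median-of-ratios scaling 11 of these rose and 12 fell, with an adjusted p of 0.577.

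Of the genes of glycolysis and lactate use in 2CLCs, Hk2 fell from 64.8 ± 0.584 to 6.34 ± 1.18 FPKM, Pdk1 from 25.3 ± 0.971 to 1.18 ± 0.229, and Ldha, which encodes the lactate dehydrogenase A subunit, from 614 ± 10.3 to 234 ± 11.5. The lactate transporter gene Slc16a1 stood at 27.3 ± 1.41 FPKM in 2CLCs and 53.9 ± 1.67 in ESCs. Its log2 fold change was -0.96, or -0.50 relative to all genes, and -0.20 with median-of-ratios scaling. Of 24 glycolysis genes 1, Aldoc, rose, 15 fell and 8 did not pass (median -0.69, or -0.23 relative to all genes, camera adjusted p = 0.586). Of 22 genes of lactate transport and use 1 rose, 15 fell and 6 did not pass (median -0.56, camera adjusted p = 0.453). Of 21 genes for enzymes linked to adding or removing lactyl groups 1 rose, 14 fell and 6 did not pass (median -0.52, camera adjusted p = 0.206), among them Kat5 from 20.8 ± 1.19 to 4.06 ± 0.122 FPKM and Hdac3 from 35.5 ± 0.471 to 15.8 ± 0.987. With median-of-ratios scaling these 3 lists had 4 genes up and 4 down, 9 up and 7 down, and 10 up and 9 down, and the medians of the last 2 changed sign, to 0.13 and 0.21.

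Most splicing factor genes were lower on the deposited scale. U2af2 fell from 198 ± 4.78 to 93.1 ± 1.41 FPKM and Srsf2 from 291 ± 5.8 to 90.5 ± 8.01, while Aqr rose from 42.1 ± 0.669 to 456 ± 12.7. In the core spliceosome list 4 of 69 genes rose, 62 fell and 3 did not pass (median -0.62, or -0.16 relative to all genes, camera adjusted p = 0.00163, and 0.0842 with an estimated correlation). Its direction reversed with median-of-ratios scaling (30 rose, 17 fell, median 0.13, adjusted p = 0.762). Of 26 SR genes 2 rose, 21 fell and 3 did not pass (median -0.66, camera adjusted p = 0.116). Of 48 hnRNP and regulator genes 5 rose, 34 fell and 9 did not pass (median -0.67, camera adjusted p = 0.116). These 2 medians also changed sign with median-of-ratios scaling, to 0.06 and 0.05.

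In a list of repressors of the 2C programme and chromatin genes, which also holds the activators Nelfa and Dppa2, Max fell from 48.8 ± 0.913 to 9.6 ± 0.309 FPKM, while Nelfa rose from 28.8 ± 0.293 to 907 ± 27.4 and Dppa2 from 54.7 ± 3.21 to 227 ± 18.6. In that list 2 of 32 genes rose, 25 fell and 5 did not pass (median -0.90, camera adjusted p = 0.0541), and with median-of-ratios scaling 9 rose and 16 fell (median -0.15). In the DNA methylation list 12 of 14 genes fell, Tet2 among them from 40.8 ± 1.84 to 4.25 ± 1.19 FPKM, and 2 did not pass (median -1.11, camera adjusted p = 0.0749). With median-of-ratios scaling 3 of these rose and 9 fell (median -0.49).

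Mitochondrially encoded and ribosomal protein genes were higher in 2CLCs on the deposited scale. mt-Co1 rose from 3020 ± 54.3 to 6300 ± 283 FPKM, mt-Atp6 from 2240 ± 27.6 to 5070 ± 179 and Rplp0 from 1020 ± 14.3 to 1910 ± 117, but with quantile normalization these reversed to -0.51, -0.21 and -0.05. All 13 mitochondrially encoded genes rose (median 0.93, camera adjusted p = 7.05e-08, and 0.0275 with an estimated correlation). The list reversed at an adjusted p of 0.974 under quantile normalization. Of 77 ribosomal protein genes 55 rose, Rpl17 fell (adjusted p = 0.424 with median-of-ratios scaling) and 21 did not pass (median 0.38, camera adjusted p = 2.41e-09, and 0.684 with an estimated correlation). The list reversed at 0.0511 under quantile normalization. Of 73 oxidative phosphorylation genes 7 rose, 39 fell and 27 did not pass (median -0.21, or 0.25 relative to all genes, camera adjusted p = 0.874), and with median-of-ratios scaling 62 rose and 1 fell.

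Fibroblast genes stayed low in 2CLCs: Col1a1 stood at 0.561 ± 0.282 FPKM against 0.209 ± 0.0615 in ESCs and 310 ± 2.42 in MEFs, and Col6a1 rose from 0.0217 ± 0.0377 to 1.36 ± 0.195. In this list 10 of 38 genes rose, 9 fell and 19 did not pass (median 0.02, camera adjusted p = 0.0177, and 0.0842 with an estimated correlation). With median-of-ratios scaling 16 rose and 2 fell, and the list call was lost (adjusted p = 0.247), as with quantile normalization (0.133) and a fit of only the compared groups (0.0641). The heat-shock gene Hspa1a rose from 0.925 ± 0.624 to 20.4 ± 0.469 FPKM. Of the 30 lists 4 were called up, 2 down and 24 not called, with adjusted p-values from 0.0541 to 0.964 for the last. For 8 of these the test, which is relative to all genes, pointed up while median and mean were negative: the trophectoderm, mesoderm, neural, osmotic stress, p53, hypoxia, oxidative phosphorylation and immediate early lists. Adjusted over the list alone, 7 fibroblast, 38 oxidative phosphorylation and 17 sterol synthesis genes fell in place of 9, 39 and 16, 5 ATF4 genes rose in place of 4, and the other counts were equal. The structured RNA Rn7sk, which carries no poly(A) tail, stood at 51.9, 44.9 and 68.4 FPKM in the 3 2CLC libraries and at 3.24, 2.93 and 2.17 in the ESC libraries.

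**Figure D2:**
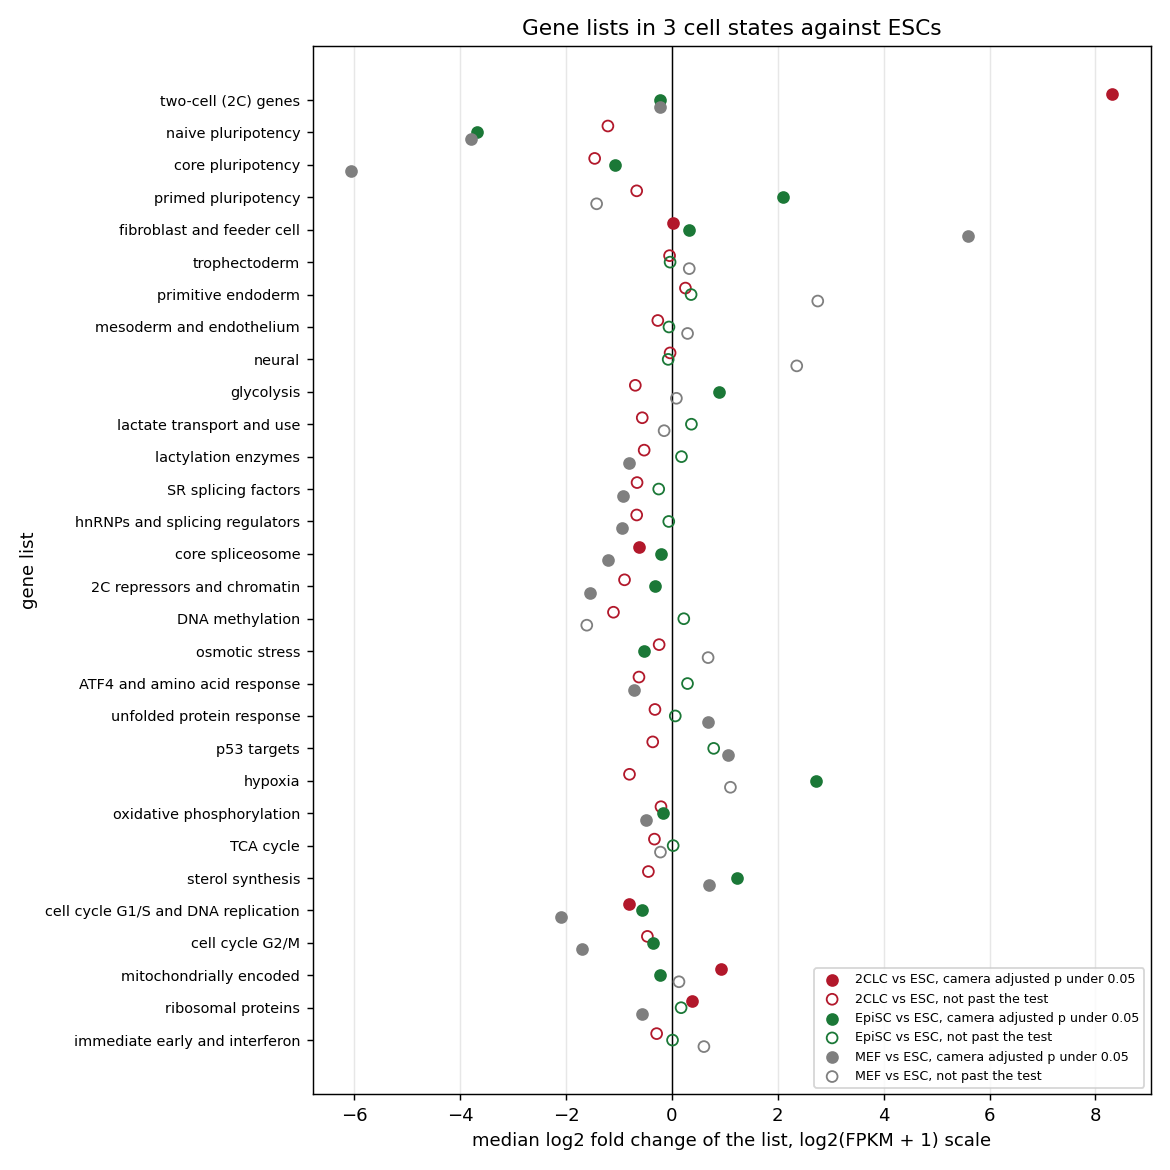
Median log2 fold change of 30 gene lists on the log2(FPKM + 1) scale in 2CLCs, EpiSCs and MEFs against ESCs, with filled points where the camera adjusted p is under 0.05. The 2C list lies at 8.32 in 2CLCs. Subtracting the median of all genes would shift every 2CLC point right by about 0.46, which does not stand in for rescaling. With median-of-ratios scaling the core spliceosome point moves from -0.62 to 0.13 and the fibroblast point only from 0.02 to 0.11. With quantile normalization the mitochondrially encoded and ribosomal protein lists reverse.

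EpiSCs were compared with ESCs to set primed against naive pluripotency. Zfp42 fell from 318 ± 1.37 FPKM in ESCs to 0.0307 ± 0.0532 in EpiSCs (SD, n = 3; log2 fold change -8.27, adjusted p = 2.26e-14), Esrrb from 285 ± 5.79 to 0.699 ± 0.279 and Dppa5a from 513 ± 1.76 to 0.259 ± 0.225. Otx2, a transcription factor gene of primed cells, rose from 1.18 ± 0.124 to 93.2 ± 14.8 FPKM (5.42, adjusted p = 2.74e-10), and Fgf5 rose from 0.0449 ± 0.0405 to 36.2 ± 9.92. Of the 32 naive pluripotency genes 31 fell and 1, Mkrn1, did not pass (median -3.68, camera adjusted p = 2.21e-21, and 0.0271 with an estimated correlation). Of 25 primed pluripotency genes 19 rose, 3 fell and 3 did not pass (median 2.11, camera adjusted p = 2.44e-05, and 0.13 with an estimated correlation). Zfp42 lies on chromosome 8 at 43295063 to 43306980, Otx2 on chromosome 14 at 48657677 to 48673819 and Fgf5 on chromosome 5 at 98254184 to 98277030.

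Among further naive genes Klf4 fell from 69.4 ± 1.16 to 0.95 ± 0.434 FPKM, Tfcp2l1 from 59.6 ± 2.28 to 0.41 ± 0.106 and Nanog from 277 ± 1.85 to 29.3 ± 5.9. Pou5f1 changed little, from 779 ± 3.4 to 677 ± 88.2 FPKM (log2 fold change -0.21, adjusted p = 0.0412), and its call was lost under 6 alternatives with adjusted p-values up to 0.128. Sox2 fell from 131 ± 1.22 to 36.7 ± 11.4 FPKM, Gdf3 from 95.6 ± 2.37 to 0.841 ± 1.02 and Dppa2 from 54.7 ± 3.21 to 0.693 ± 0.128, while the adhesion gene Epcam rose from 26.9 ± 0.992 to 184 ± 18.2. Of 18 core pluripotency genes 4 rose, 12 fell and 2 did not pass (median -1.07, camera adjusted p = 0.018, and 0.556 with an estimated correlation). Pim2 rose from 4.04 ± 0.324 to 456 ± 190 FPKM and Krt18 from 3.03 ± 0.516 to 211 ± 30.1, while Lefty2 fell from 54.3 ± 5.01 to 9.29 ± 2.57.

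The de novo DNA methyltransferase gene Dnmt3b rose from 25.5 ± 0.804 to 380 ± 84.8 FPKM, and its partner Dnmt3l fell from 122 ± 6.29 to 0.293 ± 0.203. In the DNA methylation list 6 of 14 genes rose, 5 fell and 3 did not pass (camera adjusted p = 0.835), with a positive median of 0.22 and a negative mean of -0.36. Zfp57 fell from 281 ± 5.08 to 26.6 ± 1.73 FPKM. Of 32 2C repressor and chromatin genes 4 rose, 20 fell and 8 did not pass (median -0.32, camera adjusted p = 0.000175, and 0.514 with an estimated correlation). Zscan4c was at 2.34 ± 0.2 FPKM in ESCs and listed at 0 in all 3 EpiSC libraries. Of the 53 2C genes Eif4e3 rose, from 0.29 ± 0.0634 to 4.29 ± 0.678 FPKM, 28 fell and 24 did not pass (median -0.23, camera adjusted p = 1.23e-06, and 0.057 with an estimated correlation). Many 2C genes already stood under 1 FPKM in ESCs, so their falls lie near the floor.

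Glycolysis and hypoxia genes were higher in EpiSCs, with EpiSC replicate 1 apart from the other replicates. The lactate exporter gene Slc16a3 rose from 3.87 ± 0.261 to 171 ± 49.6 FPKM, Ldha from 614 ± 10.3 to 1320 ± 519 and Pkm from 854 ± 1.36 to 1630 ± 411. Slc2a1 stood at 90.4, 494 and 508 FPKM in the 3 EpiSC libraries against 54.7 ± 0.471 in ESCs, Bnip3 at 36.4, 181 and 191 against 3.49 ± 0.488 and Ddit4 at 50.8, 422 and 422 against 6.99 ± 1.05. Vegfa rose from 5.21 ± 0.31 to 46.2 ± 25.6 FPKM. Pdk1 did not pass the test at 45.8 ± 24.3 against 25.3 ± 0.971 FPKM (adjusted p = 0.144) and passed without EpiSC replicate 1 (log2 fold change 1.21, adjusted p = 6.74e-07). Of 23 hypoxia genes 18 rose and 5 did not pass (median 2.72, camera adjusted p = 0.00235, and 0.7 with an estimated correlation). Of 24 glycolysis genes 15 rose, 1, Galm, fell and 8 did not pass (median 0.88, camera adjusted p = 0.00507, and 0.699 with an estimated correlation). Between libraries, EpiSC replicate 1 had a Pearson r across genes of 0.9733 and 0.9726 with the other replicates, which had 0.9955 with each other; genes are not independent replicates.

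Sterol synthesis genes rose together: Cyp51 from 16.4 ± 0.844 to 95.3 ± 2.59 FPKM and Insig1 from 22.8 ± 0.732 to 109 ± 10.5. Of the 25 genes 24 rose and Ebp fell (median 1.22, camera adjusted p = 1.31e-07, and 0.148 with an estimated correlation). In the fibroblast list 21 of 38 genes rose, 4 fell and 13 did not pass (median 0.32, camera adjusted p = 0.011, and 0.072 with an estimated correlation), with Lgals1 up from 14.2 ± 1.05 to 100 ± 9.35 FPKM, Col1a2 from 0.0516 ± 0.0465 to 1.94 ± 0.223 and Fn1 down from 110 ± 4.52 to 35.6 ± 1.29. The epithelial splicing regulator Esrp1 rose from 1.15 ± 0.15 to 30.8 ± 6.12 FPKM, Cdc5l fell from 111 ± 0.515 to 28.5 ± 5.53 and Dhx16 fell from 74.7 ± 2.57 to 31.6 ± 1.52. Of 69 core spliceosome genes 8 rose, 38 fell and 23 did not pass (median -0.21, camera adjusted p = 0.000501, and 0.072 with an estimated correlation). In the SR list 6 of 26 rose and 12 fell (camera adjusted p = 0.283), and in the hnRNP list 10 of 48 rose and 16 fell (camera adjusted p = 0.508).

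Cell-cycle and osmotic genes were lower in EpiSCs. Ccnd3 fell from 142 ± 3.56 to 50.6 ± 5.45 FPKM and Ccne1 from 123 ± 1.02 to 58.5 ± 14.8. Of 29 G1/S genes 1 rose, 24 fell and 4 did not pass (median -0.57, camera adjusted p = 1.25e-05, and 0.057 with an estimated correlation). Of 26 G2/M genes 3 rose, 13 fell and 10 did not pass (median -0.35, camera adjusted p = 0.0476, and 0.782 with an estimated correlation). Sgk1 fell from 172 ± 2.86 to 20.7 ± 7.18 FPKM, Aqp3 from 9.54 ± 0.648 to 0.0136 ± 0.0235 and Akr1b3 from 306 ± 6.36 to 103 ± 5.69. Of 21 osmotic stress genes 3 rose, 12 fell and 6 did not pass (median -0.53, camera adjusted p = 0.0056, and 0.072 with an estimated correlation). Of 73 oxidative phosphorylation genes 4 rose, 32 fell and 37 did not pass (median -0.17, camera adjusted p = 0.00575, and 0.724 with an estimated correlation). Of 13 mitochondrially encoded genes 8 fell and 5 did not pass (median -0.23, camera adjusted p = 0.0474, and 0.358 with an estimated correlation).

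In all, 9765 of 16358 genes changed between EpiSCs and ESCs, 5438 higher and 4327 lower, with 2106 and 1292 differing by at least 1 on the log2 scale; without EpiSC replicate 1 the calls numbered 10657. Of the 30 lists 5 were called up, 10 down and 15 not called, the last with adjusted p-values from 0.0558 to 0.964. Without EpiSC replicate 1 the ribosomal protein, p53, ATF4 and SR lists gained a call (camera adjusted p = 2.04e-05, 0.00152, 0.0134 and 0.0499). The oxidative phosphorylation and mitochondrially encoded lists lost theirs (0.124 and 0.188). Median and mean also differed in sign, or from the test, for the trophectoderm, mesoderm, lactylation enzyme, hnRNP and TCA cycle lists, none of them called. Adjusted over the list alone, 27 2C, 13 core pluripotency, 4 primed, 6 DNA methylation, 1 hypoxia and 31 oxidative phosphorylation genes fell, 16 glycolysis, 10 lactate use, 21 ATF4, 19 p53 and 10 immediate early genes rose, and 0 ribosomal protein genes rose in place of 15.

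MEFs were compared with ESCs as a differentiated cell type. Bgn, which encodes the matrix protein biglycan, stood at 841 ± 19.9 FPKM in MEFs and 0.0242 ± 0.0222 in ESCs (SD, n = 3; log2 fold change 9.68, adjusted p = 1.77e-14). Col1a1 rose from 0.209 ± 0.0615 to 310 ± 2.42 FPKM, Col1a2 from 0.0516 ± 0.0465 to 394 ± 8.86 and Acta2 from 0.0197 ± 0.0342 to 581 ± 11.9. All 38 measured fibroblast genes rose (median 5.59, camera adjusted p = 4.66e-19, and 0.000277 with an estimated correlation). Pou5f1 was at 779 ± 3.4 FPKM in ESCs and listed at 0 in all 3 MEF libraries, and all 18 core pluripotency genes fell (median -6.06, camera adjusted p = 5.67e-09, and 0.0842 with an estimated correlation). Bgn lies on chromosome X at 73483602 to 73495933, Col1a1 on chromosome 11 at 94936224 to 94953042 and Pou5f1 on chromosome 17 at 35506018 to 35510772.

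Vim rose from 101 ± 1.75 to 1520 ± 42.5 FPKM, Thy1 from 1.07 ± 0.295 to 73.9 ± 7.35 and Col3a1 from 0.00725 ± 0.00646 to 81 ± 6.21, and S100a4 was at 403 ± 7.68 FPKM in MEFs and listed at 0 in all ESC libraries. Nanog fell from 277 ± 1.85 to 0.0405 ± 0.0351 FPKM, Sox2 from 131 ± 1.22 to 0.741 ± 0.185, Esrrb from 285 ± 5.79 to 0.0154 ± 0.0144 and Klf4, which fibroblasts also express, from 69.4 ± 1.16 to 13.1 ± 0.387. Lin28a was at 117 ± 3.04 FPKM in ESCs and Tdgf1 at 250 ± 3.15, and both were listed at 0 in all MEF libraries. Of 32 naive pluripotency genes the cytokine receptor gene Il6st rose, from 7.22 ± 0.063 to 31.1 ± 0.871 FPKM, 30 fell and 1 did not pass (median -3.80, camera adjusted p = 1.24e-10, and 0.072 with an estimated correlation). Zscan4c at 2.34 ± 0.2 FPKM and Zscan4f at 3.75 ± 0.0173 in ESCs were listed at 0 in all MEF libraries. Of 53 2C genes 3 rose, Rxra among them from 6.25 ± 0.132 to 17.1 ± 1.28 FPKM, 31 fell and 19 did not pass (median -0.22, camera adjusted p = 0.00579, and 0.22 with an estimated correlation). As in EpiSCs, many of the falls lie near the floor, since the genes stood under 1 FPKM in ESCs.

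Proliferation genes were lower in MEFs. Mcm5, a subunit of the replicative helicase, fell from 255 ± 4.31 to 15.6 ± 0.232 FPKM, Ccnb1 from 160 ± 2.78 to 27.2 ± 0.518 and Uhrf1 from 154 ± 2.32 to 20 ± 0.719, while the cyclin genes Ccnd1 and Ccnd2 rose from 63.6 ± 0.704 to 386 ± 5.76 and from 9.35 ± 0.82 to 166 ± 1.83. Of 29 G1/S genes 2 rose, 26 fell and 1, E2f1, did not pass (median -2.10, camera adjusted p = 1.31e-07, and 0.0275 with an estimated correlation), and all 26 G2/M genes fell (median -1.69, camera adjusted p = 5.04e-07, and 0.506 with an estimated correlation). The p53 target genes Cdkn1a and Ccng1 rose from 26.6 ± 0.637 to 236 ± 2.81 and from 43.3 ± 2 to 315 ± 11.3 FPKM. Of 29 genes of this list 20 rose, 7 fell and 2 did not pass (median 1.05, camera adjusted p = 0.0341, and 0.74 with an estimated correlation). Of 32 2C repressor and chromatin genes 1, E2f6, rose, 28 fell and 3 did not pass (median -1.54, camera adjusted p = 2.48e-07, and 0.335 with an estimated correlation).

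Splicing genes were lower in MEFs as a class. Cdc5l fell from 111 ± 0.515 to 16 ± 0.693 FPKM and Xab2 from 55.7 ± 3.48 to 9.82 ± 0.268. Of 69 core spliceosome genes 66 fell and 3 did not pass (median -1.21, camera adjusted p = 4.99e-13, and 0.00521 with an estimated correlation). Srsf7 fell from 204 ± 25.9 to 54.9 ± 0.808 FPKM and Srsf3 from 191 ± 1.25 to 61.8 ± 0.879. Of 26 SR genes 3 rose, 20 fell and 3 did not pass (median -0.92, camera adjusted p = 0.00828, and 0.501 with an estimated correlation). Hnrnpa1 fell from 527 ± 6.84 to 201 ± 8.87 FPKM and the muscleblind gene Mbnl2 rose from 3.33 ± 0.425 to 61.7 ± 1.35. Of 48 hnRNP and regulator genes 5 rose, 41 fell and 2 did not pass (median -0.94, camera adjusted p = 7.19e-05, and 0.243 with an estimated correlation). Of 21 lactylation enzyme genes 3 rose, Sirt2 among them from 9.61 ± 0.114 to 45 ± 0.56 FPKM, 16 fell and 2 did not pass (median -0.81, camera adjusted p = 0.00831, and 0.072 with an estimated correlation); Aars fell from 162 ± 1.65 to 49.7 ± 0.293 and Kat2b from 20.3 ± 0.622 to 2.79 ± 0.133.

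Protein-making genes were lower and secretory stress genes higher in MEFs. Rpl4 fell from 1010 ± 7.87 to 593 ± 6.72 FPKM. Of 77 ribosomal protein genes 71 fell and 6 did not pass (median -0.57, camera adjusted p = 1.36e-05, and 0.724 with an estimated correlation). Asns fell from 187 ± 1.03 to 25.5 ± 0.112 FPKM and Slc7a3 from 66.1 ± 1.26 to 0.686 ± 0.2, while Cebpb rose from 1.16 ± 0.0501 to 10.8 ± 4.55. Of 36 ATF4 genes 9 rose, 25 fell and 2 did not pass (median -0.72, camera adjusted p = 0.00831, and 0.514 with an estimated correlation). Cox4i1 fell from 433 ± 4.93 to 268 ± 5.39 FPKM and Cyc1 from 147 ± 4.8 to 51.5 ± 0.741. Of 73 oxidative phosphorylation genes 1 rose, 56 fell and 16 did not pass (median -0.49, camera adjusted p = 6.68e-05, and 0.684 with an estimated correlation). Xbp1 rose from 12.7 ± 0.467 to 47.1 ± 1.68 FPKM and Dnajc3 from 5.77 ± 0.223 to 22.7 ± 0.951. Of 21 unfolded protein response genes 17 rose, 1, Creld2, fell and 3 did not pass (median 0.68, camera adjusted p = 0.00107, and 0.0675 with an estimated correlation). Of 25 sterol synthesis genes 15 rose, 4 fell and 6 did not pass (median 0.69, camera adjusted p = 0.0209, and 0.623 with an estimated correlation).

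In all, 12319 of 16358 genes changed between MEFs and ESCs, 5633 higher and 6686 lower, with 3466 and 3352 differing by at least 1 on the log2 scale. With median-of-ratios scaling the split reversed to 6671 higher and 5320 lower, while with quantile normalization it was 5454 and 6978. The median of the ribosomal protein list moved to -0.24 with median-of-ratios scaling and that of oxidative phosphorylation to -0.17. Of the 30 lists 4 were called up, 13 down and 13 not called, the last with adjusted p-values from 0.0533 to 0.798. Glycolysis had a median of 0.08 and a mean of -0.02 (camera adjusted p = 0.529). Adjusted over the list alone, 27 2C genes fell in place of 31, 72 ribosomal protein genes fell in place of 71, and 3 mitochondrially encoded genes rose and 2 fell in place of 4 and 3.

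ESCs with 60 mM sodium lactate were compared with ESCs at 0 mM to ask what lactate, the product of glycolysis that also serves to modify proteins, changes in them. Dppa3, a gene of the early embryo and of naive cells, rose from 2.64 ± 0.17 to 21.8 ± 0.766 FPKM (SD, n = 3; log2 fold change 2.65, adjusted p = 3.35e-09). Trim43a rose from 2.78 ± 0.637 to 26 ± 1.51 FPKM and Zscan4c from 16 ± 0.385 to 34 ± 1.63 (log2 fold changes 2.84 and 1.04). Lgals3, a galectin gene, fell from 40.6 ± 0.991 to 8 ± 0.253 FPKM and Apoe from 392 ± 14.3 to 113 ± 7.29. Of 46 measured 2C genes 45 rose and 1, Rxra, did not pass (median 0.97, camera adjusted p = 9.62e-21, and 0.0257 with an estimated correlation). Dppa3 lies on chromosome 6 at 122626410 to 122630272, Trim43a on chromosome 9 at 88580891 to 88588819, Lgals3 on chromosome 14 at 47367751 to 47386160 and Apoe on chromosome 7 at 19696109 to 19699188.

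Among further genes with the largest changes at 60 mM, Fabp5 rose from 15.2 ± 0.88 to 71.2 ± 3.19 FPKM, Bhmt from 3.07 ± 0.227 to 13.7 ± 0.824, and Pramel6 and Pramel7, which have near-identical relatives, from 9.3 ± 0.751 to 38.7 ± 2.39 and from 8.05 ± 1.48 to 33.3 ± 1.19. Enox1 fell from 17.2 ± 0.489 to 3.71 ± 0.483 FPKM, Ephx2 from 15.6 ± 0.212 to 3.65 ± 0.55 and the RNA sensor gene Ddx58 from 17.3 ± 0.96 to 4.38 ± 0.134. In the 2C list Tcstv3 rose from 2.21 ± 0.637 to 5.88 ± 0.739, Zfp352 from 0.515 ± 0.0345 to 2.15 ± 0.302 and Sp110 from 1.94 ± 0.424 to 7.75 ± 0.469. Pluripotency genes moved in both directions at 60 mM: Nanog rose from 237 ± 8.94 to 284 ± 4.51, Klf4 from 63.2 ± 1.62 to 83 ± 2.7 and Sox2 from 185 ± 1.79 to 231 ± 8.93, Pou5f1 fell from 740 ± 15.3 to 669 ± 3.36, and Esrrb fell from 234 ± 25.6 to 186 ± 20.6 (adjusted p = 0.0132, and 0.0502 without 0 mM replicate 3). Gbx2 fell from 12.4 ± 0.987 to 4.41 ± 0.139 FPKM, Nr0b1 from 53.8 ± 0.162 to 23.1 ± 1.44, Lin28a from 47.1 ± 1.36 to 26.3 ± 1.16 and L1td1 from 257 ± 5.72 to 161 ± 4.38, while Otx2 rose from 3.83 ± 0.276 to 11.2 ± 0.51.

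By list at 60 mM, 16 of 32 naive genes rose, 11 fell and 5 did not pass (median 0.09, camera adjusted p = 0.618), and 7 of 18 core genes rose, 10 fell and 1, Rest, did not pass (median -0.12, camera adjusted p = 0.16). ATF4 target genes, which answer amino acid shortage, fell as a class: Nupr1 from 13.8 ± 1.4 to 3.5 ± 0.424 FPKM, Atf5 from 17.3 ± 1.26 to 6.62 ± 0.356 and Atf4 from 127 ± 5.78 to 102 ± 2.09, while Ddit4 rose from 6.31 ± 0.426 to 12.3 ± 0.392. Of 34 such genes 1 rose, 27 fell and 6 did not pass (median -0.34, camera adjusted p = 1.3e-10, and 0.114 with an estimated correlation). Among p53 targets Pmaip1 rose from 11.7 ± 1.68 to 29.1 ± 2.08 FPKM, Cdkn1a from 80.9 ± 3.56 to 115 ± 11.6 and Mdm2 from 41.9 ± 1.89 to 55.7 ± 4.49. Of 27 genes of this list 15 rose, 1, Gdf15, fell and 11 did not pass (median 0.22, camera adjusted p = 0.00758, and 0.242 with an estimated correlation). Uqcrq fell from 68.4 ± 1.6 to 53.6 ± 2.57 FPKM and Atp5e from 119 ± 3.3 to 91.7 ± 6.99, and Cycs rose from 32.3 ± 0.98 to 36.2 ± 1.38. Of 73 oxidative phosphorylation genes 3 rose, 43 fell and 27 did not pass (median -0.16, camera adjusted p = 2.32e-07, and 0.122 with an estimated correlation).

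Replication and splicing genes shifted by small amounts at 60 mM. Pola1 fell from 17.8 ± 0.687 to 11.4 ± 0.712 FPKM and Top2a from 90.4 ± 1.94 to 70.8 ± 1.72. Of 28 G1/S genes 3 rose, 15 fell and 10 did not pass (median -0.12, camera adjusted p = 0.00981, and 0.242 with an estimated correlation). Of 26 G2/M genes 2 rose, 13 fell and 11 did not pass (median -0.12, camera adjusted p = 0.0103, and 0.281 with an estimated correlation). Prpf31 fell from 46.6 ± 2.48 to 35 ± 0.334 FPKM and Cdc5l rose from 98.3 ± 0.564 to 136 ± 2.25. Of 69 core spliceosome genes 8 rose, 24 fell and 37 did not pass (median -0.07, camera adjusted p = 0.018, and 0.242 with an estimated correlation). The SR list (10 of 27 up, 4 down, median 0.01) and the hnRNP list (6 of 48 up, 12 down, median -0.02) did not pass, with camera adjusted p-values of 0.823 and 0.3. Etv4 fell from 36.5 ± 2.33 to 11.4 ± 0.559 FPKM and Myc from 29.9 ± 1.87 to 20.8 ± 1.83. Of 16 immediate early and interferon genes 3 rose, 7 fell and 6 did not pass (median -0.16, camera adjusted p = 0.0303, 0.0746 with quantile normalization and 0.303 with an estimated correlation).

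Genes of lactate handling did not move as a class relative to other genes at 60 mM. Ldha rose from 326 ± 22.8 to 404 ± 5.07 FPKM, Slc2a3 from 188 ± 7.38 to 315 ± 8.62 and Slc16a1 from 32.7 ± 0.496 to 37.1 ± 0.67, while Pdk1 fell from 8.8 ± 0.461 to 4.74 ± 0.338. Of 24 glycolysis genes 8 rose, 10 fell and 6 did not pass (median 0.01 and mean 0.04 with the test pointing down, camera adjusted p = 0.706). Of 21 genes of lactate transport and use 5 rose, 7 fell and 9 did not pass (median -0.09, camera adjusted p = 0.318, and 0.00109 downward with fry). Aars fell from 170 ± 2.17 to 131 ± 1.03 FPKM, Kat2b fell from 17.9 ± 0.509 to 11.6 ± 0.507 and Hdac1 rose from 205 ± 4.17 to 249 ± 3.9. Of 21 lactylation enzyme genes 4 rose, 8 fell and 9 did not pass (median -0.05, camera adjusted p = 0.476, and 0.0248 downward with fry). Osmotic stress genes were read because the treatment is a sodium salt. Sgk1 rose from 102 ± 4.57 to 181 ± 4.61 FPKM and Slc38a2 from 46.9 ± 1.58 to 53.5 ± 1.59, Akr1b3 fell from 249 ± 6.63 to 212 ± 6.11, and Nfat5 did not pass the test at 8.27 ± 1.11 against 8.98 ± 2.41 (adjusted p = 0.676). In that list 8 of 16 rose, 3 fell and 5 did not pass (median 0.09, camera adjusted p = 0.476, and 0.00161 upward with fry). Most of the 30 lists passed with fry at 60 mM, in either direction. Cdx2 rose from 1.67 ± 0.0958 to 3.85 ± 0.193 FPKM and Gata3 from 2.61 ± 0.368 to 6.46 ± 0.338, and the trophectoderm list did not pass (6 of 10 up, 1 down, camera adjusted p = 0.0699).

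In all, 5591 of 13271 genes changed at 60 mM, 3117 higher and 2474 lower, of which 152 and 80 differed by at least 1 on the log2 scale. The structured RNAs stood apart in 1 library: Rn7sk was at 27.3 FPKM in 60 mM replicate 1 and at 1.71 and 1.26 in the others, against a mean of 0.611 at 0 mM. Of the 30 lists 2 were called up, 6 down and 22 not called, the last with adjusted p-values from 0.0699 to 0.995. Adjusted over the list alone, 46 2C, 18 naive, 7 primed, 10 glycolysis, 6 lactylation enzyme and 2 ATF4 genes rose, 9 lactate use, 5 SR, 25 core spliceosome, 2 p53, 10 2C repressor, 46 oxidative phosphorylation and 8 immediate early genes fell, 8 sterol synthesis genes rose and 8 fell, 4 G1/S genes rose and 16 fell, and 10 ribosomal protein genes rose and 4 fell. Medians and means differed in sign from each other or from the test in the fibroblast, 2C repressor, sterol and glycolysis lists, none of them called.

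At 80 mM Dppa3 rose from 2.64 ± 0.17 to 36.7 ± 2.21 FPKM (SD, n = 3; log2 fold change 3.37, adjusted p = 6.67e-10), Trim43a from 2.78 ± 0.637 to 40.8 ± 0.405 and Zscan4c from 16 ± 0.385 to 51.9 ± 1.92. The imprinted RNA H19 rose from 5.63 ± 1.1 to 35.9 ± 7.33 FPKM (2.47). Lgals3 fell from 40.6 ± 0.991 to 7.8 ± 0.546 FPKM and Enox1 from 17.2 ± 0.489 to 1.77 ± 0.0302. All 46 measured 2C genes rose (median 1.55, camera adjusted p = 3.18e-21, and 0.0257 with an estimated correlation), and they held 0.0524% of all FPKM at 0 mM, 0.112% at 60 mM and 0.17% at 80 mM. As at 60 mM, the filter favoured a rise for members under 1 FPKM at 0 mM. H19 lies on chromosome 7 at 142575529 to 142578143.

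**Figure D3:**
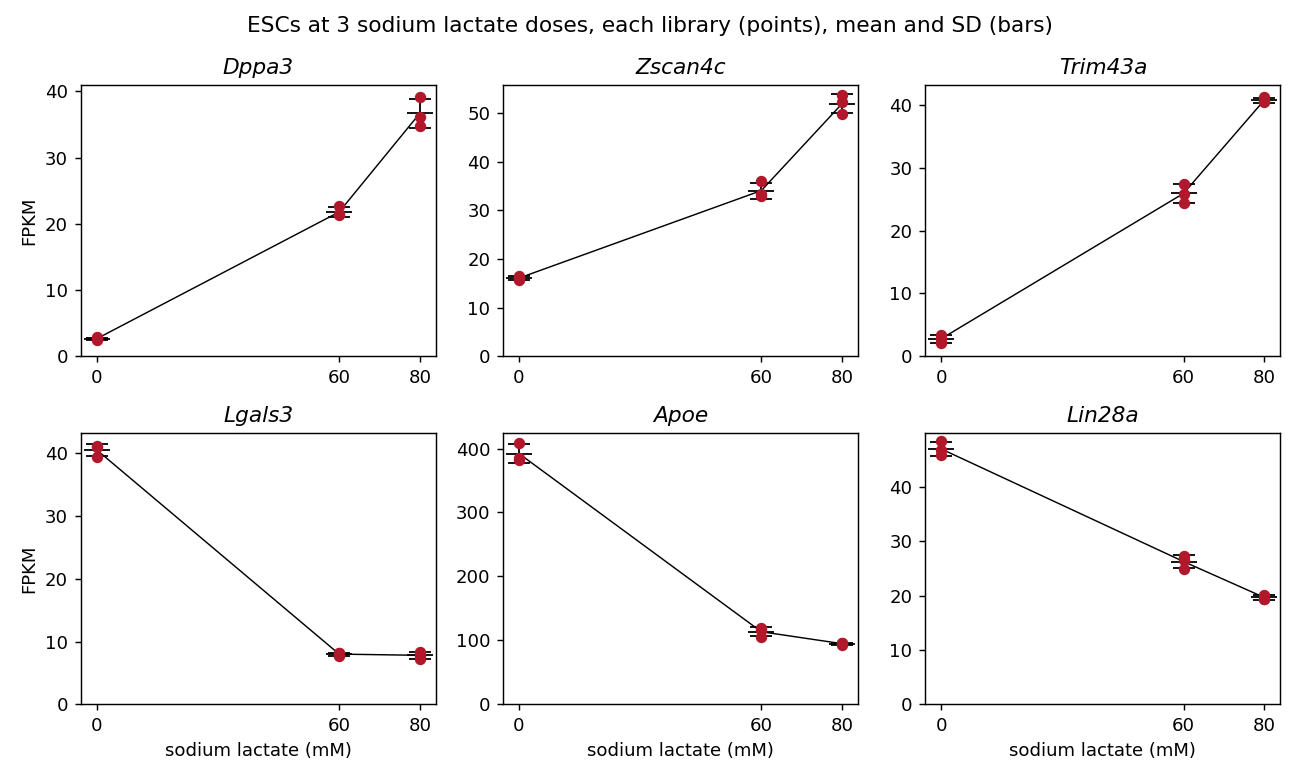
FPKM of 6 genes in ESCs against sodium lactate in mM, with a point for each library and bars for the mean and SD of 3. Dppa3 was at 2.64, 21.8 and 36.7 FPKM and Lgals3 at 40.6, 8 and 7.8 at 0, 60 and 80 mM.

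Further changes at 80 mM included Pramel6 from 9.3 ± 0.751 to 63 ± 4.36 FPKM, Fabp5 from 15.2 ± 0.88 to 93.2 ± 1.74 and Bhmt from 3.07 ± 0.227 to 22.6 ± 1.89 upward. Mymx fell from 56.1 ± 4.5 to 12.2 ± 0.864 FPKM, Apoe from 392 ± 14.3 to 94.7 ± 1.66, Etv4 from 36.5 ± 2.33 to 8.07 ± 1.29, Ephx2 from 15.6 ± 0.212 to 2.66 ± 0.0768 and Ddx58 from 17.3 ± 0.96 to 3.4 ± 0.355. In the 2C list Zfp352 rose from 0.515 ± 0.0345 to 4.3 ± 0.171, Tcstv3 from 2.21 ± 0.637 to 9.68 ± 0.723, Zscan4d from 6.24 ± 0.719 to 18.1 ± 2.15 and Sp110 from 1.94 ± 0.424 to 14.6 ± 0.968. Nelfa, which rises with the 2C programme, went from 34.3 ± 0.434 to 54.9 ± 0.602 FPKM and Dppa2 from 67 ± 2.02 to 95.5 ± 1.88. Uhrf1 fell from 200 ± 4.03 to 124 ± 5 FPKM. Of 32 2C repressor and chromatin genes 8 rose, 13 fell and 11 did not pass (median -0.04, camera adjusted p = 0.174).

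Pluripotency genes again moved in both directions at 80 mM. Nanog rose from 237 ± 8.94 to 293 ± 7.41 FPKM, Klf4 from 63.2 ± 1.62 to 94.9 ± 2.01 and Sox2 from 185 ± 1.79 to 237 ± 8.09, while Esrrb fell from 234 ± 25.6 to 180 ± 9.03 and Pou5f1 from 740 ± 15.3 to 675 ± 8.01. Gbx2 fell from 12.4 ± 0.987 to 2.48 ± 0.586 FPKM, Nr0b1 from 53.8 ± 0.162 to 19 ± 1.14, Lin28a from 47.1 ± 1.36 to 19.7 ± 0.463 and L1td1 from 257 ± 5.72 to 132 ± 0.628, and Otx2 rose from 3.83 ± 0.276 to 13.1 ± 1.14. Of 32 naive genes 18 rose, 11 fell and 3 did not pass (median 0.15, camera adjusted p = 0.618). Of 18 core genes 7 rose, 10 fell and 1 did not pass (median -0.15, camera adjusted p = 0.128). Among trophectoderm genes, of the lineage that makes placenta, Cdx2 rose from 1.67 ± 0.0958 to 5.05 ± 0.113 FPKM, Gata2 from 2.69 ± 0.188 to 9.61 ± 1.35 and Gata3 from 2.61 ± 0.368 to 7.56 ± 0.766. Of 10 measured trophectoderm genes 6 rose, 1, Tead4, fell and 3 did not pass (median 0.89, camera adjusted p = 0.0149, 0.171 with an estimated correlation and 0.0751 with a filter of 5 FPKM).

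Atf5 fell from 17.3 ± 1.26 to 6.96 ± 1.2 FPKM and Nupr1 from 13.8 ± 1.4 to 5.24 ± 1.92 at 80 mM, while Ddit4 rose from 6.31 ± 0.426 to 17.3 ± 0.301. Of 34 ATF4 genes 3 rose, 26 fell and 5 did not pass (median -0.29, camera adjusted p = 1e-07, and 0.142 with an estimated correlation). Pmaip1 rose from 11.7 ± 1.68 to 30.6 ± 1.27 FPKM and Cdkn1a from 80.9 ± 3.56 to 130 ± 5.61. Of 27 p53 targets 16 rose, 2 fell and 9 did not pass (median 0.26, camera adjusted p = 0.0084, and 0.242 with an estimated correlation). Ndufs6 fell from 83.5 ± 1.52 to 60.9 ± 5.43 FPKM. Of 73 oxidative phosphorylation genes 7 rose, 43 fell and 23 did not pass (median -0.14, camera adjusted p = 1.11e-05, and 0.158 with an estimated correlation). Pcna fell from 250 ± 0.362 to 175 ± 5.99 FPKM, Ccnd1 from 19.1 ± 0.19 to 8.5 ± 0.459 and Top2a from 90.4 ± 1.94 to 59.9 ± 0.445. Of 28 G1/S genes 3 rose, 18 fell and 7 did not pass (median -0.23, camera adjusted p = 0.000132, and 0.142 with an estimated correlation). Of 26 G2/M genes 2 rose, 17 fell and 7 did not pass (median -0.17, camera adjusted p = 0.00128, and 0.239 with an estimated correlation).

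Splicing genes moved by small amounts at 80 mM. Hnrnph2 fell from 37.2 ± 2.33 to 20.4 ± 0.615 FPKM and Mbnl2 rose from 5.94 ± 0.478 to 10.9 ± 0.842. Of 48 hnRNP and regulator genes 7 rose, 21 fell and 20 did not pass (median -0.11, camera adjusted p = 0.0281, and 0.414 with an estimated correlation). Prpf31 fell from 46.6 ± 2.48 to 32 ± 0.665 FPKM and Cdc5l rose from 98.3 ± 0.564 to 148 ± 3.39. Of 69 core spliceosome genes 6 rose, 30 fell and 33 did not pass (median -0.10, camera adjusted p = 0.00145, and 0.171 with an estimated correlation). The SR list had 8 of 27 genes up, 8 down and 11 not past the test (median 0.01 and mean 0.03 with the test pointing down, camera adjusted p = 0.811).

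Glycolysis genes went both ways at 80 mM, with Slc2a3 up from 188 ± 7.38 to 372 ± 6.53 FPKM, Ldha up from 326 ± 22.8 to 415 ± 11.1 and Pdk1 down from 8.8 ± 0.461 to 3.89 ± 0.286. Of 24 genes 9 rose, 9 fell and 6 did not pass (median 0.01, mean 0.09, camera adjusted p = 0.811). Of 21 genes of lactate transport and use 9 rose, 9 fell and 3 did not pass (median -0.04, camera adjusted p = 0.642). Aars fell from 170 ± 2.17 to 125 ± 1.54 FPKM, Kat2b fell from 17.9 ± 0.509 to 10.5 ± 0.328 and Hdac1 rose from 205 ± 4.17 to 260 ± 3.87. Of 21 lactylation enzyme genes 5 rose, 8 fell and 8 did not pass (median -0.05, camera adjusted p = 0.448). Among osmotic genes the osmolyte transporter gene Slc6a12 rose from 0.179 ± 0.0552 to 1.67 ± 0.221 FPKM and Sgk1 from 102 ± 4.57 to 213 ± 6.72, Akr1b3 fell from 249 ± 6.63 to 208 ± 2.35, and Nfat5 did not pass the test at 7.59 ± 0.781 against 8.98 ± 2.41. In that list 7 of 16 rose, 4 fell and 5 did not pass (median 0.09, camera adjusted p = 0.476, and 8.23e-05 upward with fry). Most of the 30 lists passed with fry at 80 mM, in either direction. Myc fell from 29.9 ± 1.87 to 14.5 ± 0.667 FPKM, and the immediate early and interferon list did not pass (5 of 16 up, 8 down, camera adjusted p = 0.0699).

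**Figure D4:**
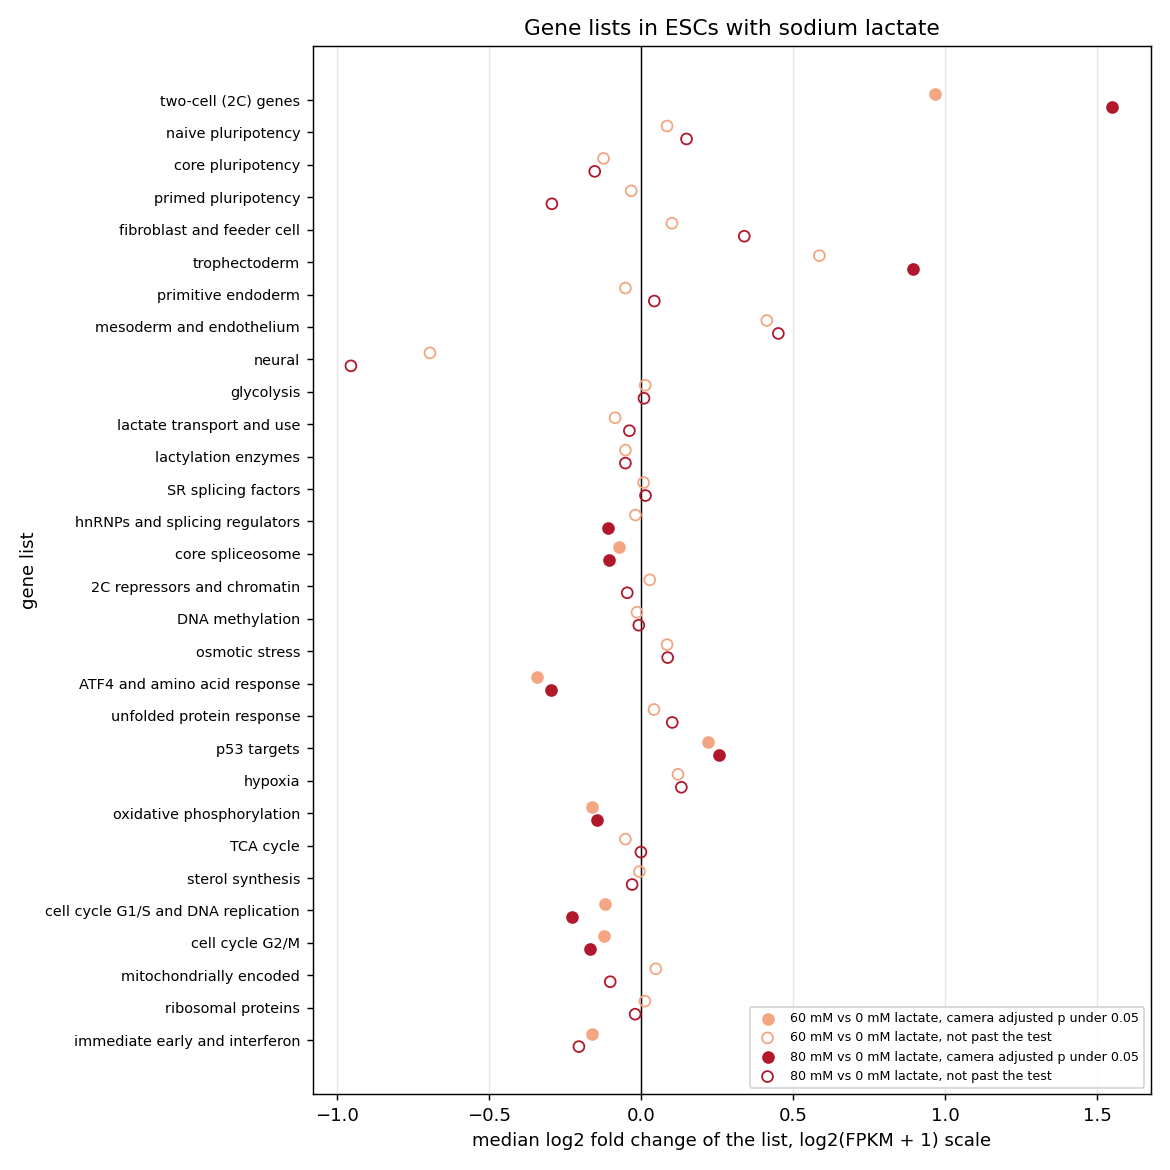
Median log2 fold change of 30 gene lists on the log2(FPKM + 1) scale at 60 and 80 mM sodium lactate against 0 mM, with filled points where the camera adjusted p is under 0.05. The 2C list lies furthest right at both doses, at 0.97 and 1.55, and the ATF4 list lies at -0.34 and -0.29.

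In all, 7041 of 13271 genes changed at 80 mM, 3977 higher and 3064 lower, of which 436 and 137 differed by at least 1 on the log2 scale. Of the 30 lists 3 were called up, 6 down and 21 not called, the last with adjusted p-values from 0.0699 to 0.811. Adjusted over the list alone, 8 fibroblast, 17 p53 and 7 TCA cycle genes rose, 10 glycolysis, 10 lactate use, 23 hnRNP, 14 2C repressor, 44 oxidative phosphorylation and 20 G1/S genes fell, 10 hypoxia genes rose and 7 fell, 13 ribosomal protein genes rose and 11 fell, and 1 mitochondrially encoded gene rose and 2 fell. Medians and means also differed in sign in the primed, primitive endoderm and sterol lists, none of them called. Of the genes called in both lactate comparisons 2871 were higher in both, 2230 lower in both and 5 opposite, where independent lists would share 934 and 571. Simulated unchanged groups with common simulated controls shared 0. With no change hardly any gene is called, so this 0 does not measure what shared controls add to the overlap. The fold changes at 60 and 80 mM had a Pearson r of 0.911 across genes, which are not independent replicates, against 0.497 in the simulations, and a covariance of 0.1405 against 0.0062, a difference of 0.1342. The simulations hold the shared controls and the independent lists do not, so part of the excess over the latter may come from the shared controls.

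Genes that set 2CLCs apart were followed in the lactate libraries to ask whether lactate moves ESCs toward that state. Of the 2046 genes higher in 2CLCs by at least 1 on the log2 scale 886 were measured with lactate. Of these, 458 rose and 73 fell at 60 mM (median 0.32, camera adjusted p = 5.06e-12) and 555 rose and 86 fell at 80 mM (median 0.48, camera adjusted p = 2.02e-14), and both calls held with an estimated correlation (adjusted p = 0.00059). Of 4194 measured genes lower in 2CLCs 878 rose and 1327 fell at 80 mM (median -0.04, camera adjusted p = 7.16e-05). Genes higher in EpiSCs and in MEFs had medians of 0.17 and 0.18 at 80 mM (camera adjusted p = 0.00286 and 0.000218). Genes lower in EpiSCs and in MEFs had medians of -0.10 and -0.09 (camera adjusted p = 0.000485 and 4.98e-07), further down than genes lower in 2CLCs, with 39.2% and 39.7% falling against 31.6%. The difference between these gene sets was not tested. By level, Zscan4c reached 51.9 FPKM at 80 mM against 5910 in 2CLCs, while Dppa3 reached 36.7 against 9.12 in 2CLCs. ESCs at 0 mM already differed between the tables, with Zscan4c at 16 and 2.34 and Dppa3 at 2.64 and 0.53 FPKM, so this is a comparison across tables normalized separately.

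ESCs at 80 mM were compared with ESCs at 60 mM for a further change with dose. Zscan4c rose from 34 ± 1.63 to 51.9 ± 1.92 FPKM (SD, n = 3; log2 fold change 0.60, adjusted p = 0.000404), Dppa3 from 21.8 ± 0.766 to 36.7 ± 2.21 and Zfp352 from 2.15 ± 0.302 to 4.3 ± 0.171. P4ha2, for a collagen-modifying enzyme, rose from 8.53 ± 0.781 to 16.5 ± 0.353 FPKM and H19 from 18.5 ± 1.68 to 35.9 ± 7.33. Of 46 2C genes 33 rose and 13 did not pass (median 0.58, camera adjusted p = 6.92e-30, and 0.0257 with an estimated correlation). Mymx fell from 22.2 ± 0.365 to 12.2 ± 0.864 FPKM and Lin28a from 26.3 ± 1.16 to 19.7 ± 0.463.

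Among the largest rises from 60 to 80 mM were Spopfm1 from 2.51 ± 0.906 to 5.72 ± 0.193 FPKM, Cyp1a1 from 6.72 ± 0.134 to 13.1 ± 0.874, Arg2 from 3.43 ± 0.622 to 7.01 ± 0.529 and Sp110 from 7.75 ± 0.469 to 14.6 ± 0.968. Adam23 fell from 15.4 ± 1.87 to 8.93 ± 1.61 FPKM, Pipox from 16.6 ± 0.974 to 11 ± 1.22 and Ntn1 from 10.5 ± 0.198 to 7.04 ± 0.504. Gata2 rose from 4.97 ± 0.214 to 9.61 ± 1.35 FPKM, Id2 from 9.46 ± 0.713 to 13.4 ± 0.58 and Cdx2 from 3.85 ± 0.193 to 5.05 ± 0.113. The Cdx2 call was lost under 6 alternatives (adjusted p from 0.0525 to 0.0872). Of 10 trophectoderm genes 3 rose and 7 did not pass (median 0.24, camera adjusted p = 0.00059, and 0.114 with an estimated correlation). Tcstv3 rose from 5.88 ± 0.739 to 9.68 ± 0.723 FPKM (adjusted p = 0.0264), a call lost under 7 alternatives with adjusted p-values from 0.0559 to 0.0919. Nanog (293 ± 7.41 against 284 ± 4.51 FPKM), Pou5f1 (675 ± 8.01 against 669 ± 3.36), Esrrb (180 ± 9.03 against 186 ± 20.6) and Atf4 (104 ± 3.12 against 102 ± 2.09) did not pass the test.

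From 60 to 80 mM Ccnd1 fell from 12.4 ± 1.04 to 8.5 ± 0.459 FPKM and Uhrf1 from 151 ± 1.32 to 124 ± 5. Of 28 G1/S genes 6 fell and 22 did not pass (median -0.08, camera adjusted p = 7.89e-06, and 0.118 with an estimated correlation). Top2a fell from 70.8 ± 1.72 to 59.9 ± 0.445 FPKM. Of 26 G2/M genes 2 fell and 24 did not pass (median -0.07, camera adjusted p = 0.000909, and 0.239 with an estimated correlation). Of 48 hnRNP and regulator genes 2 fell, Hnrnph2 among them from 24.7 ± 1.33 to 20.4 ± 0.615 FPKM, and 46 did not pass (median -0.05, camera adjusted p = 0.00264, and 0.263 with an estimated correlation). Of 69 core spliceosome genes 2 rose, 1, Lsm7, fell and 66 did not pass (median -0.04, camera adjusted p = 0.00453, and 0.216 with an estimated correlation). Both list calls were also lost with quantile normalization (adjusted p = 0.12 and 0.163), the Hnrnph2 call under 5 alternatives (0.0533 to 0.0793) and the Lsm7 call under 6 (0.0524 to 0.078). Of 27 SR genes 1 fell and 26 did not pass (median -0.03, camera adjusted p = 0.16). Nelfa rose from 43.2 ± 0.338 to 54.9 ± 0.602 FPKM. Of 32 2C repressor and chromatin genes 2 rose, 5 fell and 25 did not pass (median -0.05, camera adjusted p = 0.0103, 0.0746 with quantile normalization and 0.242 with an estimated correlation). Ddit4 rose from 12.3 ± 0.392 to 17.3 ± 0.301 FPKM, Slc2a1 from 86.9 ± 1 to 107 ± 0.231 and Slc6a12 from 0.508 ± 0.0145 to 1.67 ± 0.221. Of 21 hypoxia genes 4 rose and 17 did not pass (median 0.08, camera adjusted p = 0.0429, and 0.303 with an estimated correlation), and the call was also lost with quantile normalization (0.0719) and without 60 mM replicate 2, 80 mM replicate 2 or 80 mM replicate 3 (0.0646 to 0.0803). Of the 13 mitochondrially encoded and 77 ribosomal protein genes 0 passed the test (limma), with 2 and 7 lower at an unadjusted p under 0.05. Their lists were called down (medians -0.10 and -0.02, camera adjusted p = 0.0149 and 0.0303, and 0.659 and 0.717 with an estimated correlation). The ribosomal list reversed under quantile normalization (adjusted p = 0.379) and lost its call with fry (0.332), a filter of 5 FPKM (0.0759) and without 60 mM replicate 2 or 3 or 80 mM replicate 1 (0.0959 to 0.297). The mitochondrial call was lost with quantile normalization (0.405), fry (0.334) and without 60 mM replicate 2 (0.0842) or 80 mM replicate 1 (0.348).

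In all, 819 of 13271 genes changed between 60 and 80 mM, 539 higher and 280 lower, of which 5 and 1 differed by at least 1 on the log2 scale, and 2975 genes had an unadjusted p under 0.05. With any 1 of the 6 libraries left out the count fell to between 360 and 491 genes, 237 to 343 higher and 106 to 168 lower. Of the 30 lists 3 were called up, 7 down and 20 not called, the last with adjusted p-values from 0.0554 to 0.889. Adjusted over the list alone, 39 2C, 9 naive, 5 fibroblast, 4 trophectoderm, 6 osmotic and 2 unfolded protein response genes rose, 2 primitive endoderm, 3 neural, 2 glycolysis, 3 DNA methylation, 1 p53, 14 G1/S and 2 mitochondrially encoded genes fell, and both directions changed for core pluripotency (3 rose, 8 fell), primed (4, 3), lactate use (5, 2), hnRNP (2, 9), 2C repressor (4, 10), hypoxia (5, 1) and immediate early genes (2, 6). Median and mean differed in sign, or from the test, in the primed, mesoderm, DNA methylation and oxidative phosphorylation lists, none of them called.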

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

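No test of the difference between doses was chosen after the result was seen; the tests of near-identical copies and of a larger share of 2C-like cells were. The 2C genes rose further at 80 than at 60 mM lactate, which is a difference between the effects of both doses against the same 0 mM libraries: the median log2 fold change of 80 against 60 mM was 0.58, with 33 of 46 genes past the limma test and none lower (camera adjusted p = 6.92e-30, and 0.0257 with an estimated correlation).

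The lactate response of ESCs moved genes higher in 2CLCs upward as a set (camera adjusted p = 2.02e-14 at 80 mM). Against a redistribution of reads among near-identical copies within the list, the summed FPKM of the 2C list at 80 mM was 3.21 times that at 0 mM (660.7 to 702.8 against 204.6 to 222.4 over libraries), though copies outside the list were not summed. Against a larger share of 2C-like cells as the cause of every large rise, 28.9% of the 377 genes that rose by at least 1 (log2) and were tested in both tables were not higher in 2CLCs, 22.6% with median-of-ratios scaling. The next test took the rise of each 2C gene over its 2CLC level. A larger share and no other change was taken to put the 90th percentile over genes under 4 times the 10th. The ratio was 10.7 (95% bootstrap interval from 5.02 to 25.7, 10000 resamples). This lies above the bound of 10 set for excluding that explanation, but the interval reaches below 10. The levels also come from tables normalized separately, and the split of FPKM among near-identical copies is uncertain, so the test cannot decide. Osmotic load of the sodium salt cannot be told apart from lactate itself, because no group with another sodium salt is labelled. The osmotic stress list did not pass the test relative to other genes (camera adjusted p = 0.476), while its median was above 0 at both doses. With fry, which tests a list against no change, it passed upward at 60 mM (adjusted p = 0.00161) and 80 mM (8.23e-05). Most of the 30 lists passed with fry at both doses, in either direction, so this does not set the osmotic genes apart.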

How the results depend on the processing

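The fits without repeated names and with a library left out of the shared spread were chosen after the data were seen. Over the alternatives 4573 values of named genes kept direction and side of the threshold, 39 lost the call, 4 gained it and 4 reversed; for gene lists these were 2980, 113, 125 and 15. All 174 values of the 2CLC gene sets in the lactate table kept direction and call. The EpiSC and MEF gene sets were read under no alternative but an estimated correlation. Of the counts of called genes 270 stayed within 1.5 times the main count and 45 did not. Depth is unknown, so its limits were not measured; low genes are the least certain.

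By construction, a minimum change of 1 (log2) left fewer genes: 6385 for 2CLCs (2046 higher, 4339 lower), 3398 for EpiSCs (2106, 1292), 6818 for MEFs (3466, 3352), 232 at 60 mM (152, 80), 573 at 80 mM (436, 137), 6 for 80 against 60 mM (5, 1), and an overlap of 218. A filter of 5 FPKM tested fewer genes and gave 2133 higher in 2CLCs and 2626 higher at 80 mM. Median-of-ratios scaling, which centres the typical gene, changed the 2CLC split to 6305 higher and 5198 lower, and quantile normalization to 3828 and 8202. For 80 against 60 mM the lower genes numbered 171 with no filter and 166 with no mean trend; the cause was not tested.

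Leaving out a library gave 1729 to 3132 genes higher in 2CLCs, with 1766, 1729 and 1901 without 2CLC replicates 1, 2 and 3, where fewer genes pass the filter of 3 libraries. For 80 against 60 mM it gave 360 to 491 genes, 237 to 343 higher and 106 to 168 lower, and each library moved a count by more than 1.5 times: 360, 443 and 491 genes without 60 mM replicates 1, 2 and 3, and 360, 368 and 485 without 80 mM replicates 1, 2 and 3, since fewer libraries carry the test. EpiSCs gave 10657 genes without EpiSC replicate 1. With EpiSC replicate 1 left out of the shared spread, 13188 genes were called in 2CLCs and 12886 in MEFs, and with 60 mM replicate 1 left out, 6951 at 80 mM.

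In 2CLCs Pou5f1 reversed to 0.28 with median-of-ratios scaling, and mt-Co1, mt-Atp6 and Rplp0 to -0.51, -0.21 and -0.05 with quantile normalization; the cause was not tested. Lists in 2CLCs reversed with median-of-ratios scaling (core spliceosome, adjusted p = 0.762), with quantile normalization (mitochondrially encoded 0.974, ribosomal proteins 0.0511) and with fry, which does not compare a list with other genes (trophectoderm 0.00576, neural 2.58e-05, osmotic stress 1.06e-06, p53 0.0337, oxidative phosphorylation 0.00872, immediate early 1.37e-07). Fry also reversed mesoderm in EpiSCs (0.000561), at 60 mM (0.0419) and at 80 mM (0.00859), fibroblast at 60 mM (0.0458) and glycolysis at 80 mM (0.0198), and quantile normalization reversed ribosomal proteins for 80 against 60 mM (0.379). The 2C list lost its call in EpiSCs with an estimated correlation (0.057), and in MEFs with a pseudocount of 5 (0.144), with only the compared groups (0.209) and with an estimated correlation (0.22); the cause was not tested.

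Quantile normalization also ended calls of the core spliceosome at 60 mM (adjusted p = 0.454, median -0.07 before and -0.04 after) and 80 mM (0.216, -0.10 and -0.07), hnRNPs at 80 mM (0.451, -0.11 and -0.05), G1/S and G2/M at 60 mM (0.163, -0.12 and -0.08, and 0.113, -0.12 and -0.10), immediate early genes at 60 mM (0.0746, -0.16 and -0.21) and 2C repressors for 80 against 60 mM (0.0746, -0.05 both times). Median-of-ratios scaling ended none of these, and the G1/S and G2/M calls at 80 mM and for 80 against 60 mM were lost only with the estimated correlation; the cause was not tested. A filter of 5 FPKM ended the calls of the core spliceosome at 60 mM (0.0523) and hnRNPs at 80 mM (0.0629), quantile normalization that of SR genes in MEFs (0.0501), median-of-ratios scaling that of p53 targets in MEFs (0.0539) and a pseudocount of 5 that of fibroblast genes in EpiSCs (0.0525). The G1/S call in 2CLCs was lost under 7 alternatives besides the estimated correlation (0.054 to 0.577), G2/M in EpiSCs under 8 (0.0503 to 0.195) and mitochondrially encoded genes in EpiSCs under 7 (0.0519 to 0.191). By library, these include 2CLC replicates 1, 2 and 3 for G1/S, ESC replicate 3 and EpiSC replicates 2 and 3 for G2/M, and ESC replicate 3 and EpiSC replicate 1 for the mitochondrially encoded genes; oxidative phosphorylation in EpiSCs was lost without EpiSC replicate 1 (0.124) and with quantile normalization (0.133).

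Replicate numbers showed no strong pairing of the samples, which does not exclude pairing. Same-number correlations of deviations between groups ran from -0.030 to 0.072. A replicate block gave 12483, 9573, 12258, 5417, 6953 and 623 genes in the order of the comparisons. For 80 against 60 mM each library matched its own number best (r = 0.035, 0.008 and 0.028), and the block left 623 genes in place of 819.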

Other observations

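The tests of abundant fibroblast transcripts, of library preparation and of a single library were chosen after the results were seen, as were the gene families below.

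The 2CLC and ESC libraries differed in most tested genes, with many more lower than higher. Scaling to library totals stays open as the source of the excess of lower genes: with median-of-ratios scaling the lower calls were 0.824 times the higher ones, which that scaling brings about by centring the typical gene, and with quantile normalization 68.2% of the called genes were still lower. RNA from feeder fibroblasts has little room: the fibroblast list's median log2 fold change was 0.018, which decides nothing over members that went both ways, but the 10 fibroblast genes most abundant in MEFs were higher in 2CLCs by a median of 0.0305% of their MEF level (highest 1.12%, Col6a1), with Acta2 at 0.191 FPKM in 2CLCs and 581 in MEFs and Thbs1 at 0.911 and 468. A difference in library preparation cannot be told apart from the cell state, because it would follow the groups: over Rn7sk, Rpph1 and Rn7s1 the lowest 2CLC library was at least 1.99 times the highest other library. No biological explanation of the excess of lower genes was tested.

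Clustered histone genes, whose transcripts mostly lack poly(A) tails, were higher in 2CLCs: all 60 measured rose (median log2 fold change 3.58, and 4.14 and 3.77 with median-of-ratios scaling and quantile normalization), with a summed FPKM of 2090 ± 109 against 79.2 ± 1.2 in ESCs, 49.4 ± 9.11 in EpiSCs and 190 ± 6.15 in MEFs (SD, n = 3). All 9 Tdpoz genes rose in 2CLCs, with a summed FPKM of 828 ± 23.3 against 0.625 ± 0.0851. All 38 measured Obox entries rose, with 1220 ± 323 against 0.256 ± 0.164, and both families did so under each scaling. Only 6 Obox entries remained without pseudogene names marked -ps, and all 6 rose. In every ESC, EpiSC and MEF library the summed FPKM of each family was under 1, so members passed the filter only through 2CLCs. The direction of these counts was therefore fixed by the filter. With lactate the Tdpoz sum was 4.74 ± 0.334, 13.1 ± 1.27 and 21.8 ± 0.996 at 0, 60 and 80 mM. The Obox sum was 1.11 ± 0.107, 4.1 ± 0.47 and 4.82 ± 0.607, and the histone sum 78.2 ± 2.13, 99.8 ± 23.2 and 99.6 ± 5.4. Of 34 measured histone genes 8 rose and 1 fell at 80 mM (median 0.14, and -0.09 with quantile normalization). Hoxa and Hoxb sums were 65.6 and 56.2 in MEFs against 4.03 and 1.48 in ESCs. Sequences within these families are similar, so sums are given in place of single members.

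At 60 mM lactate, structured RNAs were high in replicate 1 alone: Rn7sk at 27.3, 1.71 and 1.26 FPKM, Rpph1 at 27, 1.2 and 1.38, Rn7s1 at 139, 5.4 and 9.04 and Rn7s2 at 118, 5.27 and 7.48 in the 3 libraries. With all libraries the folds over 0 mM were 16.5, 41.5, 6.46 and 5.21, and without replicate 1 they were 2.43, 5.43, 0.91 and 0.764. The test that 0 of the 4 stood above 10-fold without it restates these values and decides nothing about the source. No biological explanation was tested.

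At 80 mM lactate, 31 genes that rose by at least 1 (log2) in both comparisons stood above their 2CLC level, but 11 of them did so already at 0 mM, such as H19 at 5.63 FPKM against 4.32, so levels differ between the tables, which were normalized separately. Over 45 2C genes the rise at 80 mM was a median of 1.09% of the 2CLC level, with a 10th percentile of 0.493% and a 90th of 5.3%.

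For each comparison 10 splits of the 6 libraries into 3 and 3 exist, so the share of splits with a result as large is never under 0.1. The real split was the 1 split with as many called genes in each: 12516 genes for 2CLCs, 9765 for EpiSCs, 12319 for MEFs, 5591 at 60 mM, 7041 at 80 mM and 819 for 80 against 60 mM, where the highest other split gave 0, 0, 0, 1, 0 and 1.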
